A study of Mus musculus with 60 samples.

How the data were processed

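The values are the deposited counts, which the authors provide as integers per transcript for each of 60 libraries. Per the submitters' processing notes, reads were processed with CASAVA 1.8.2, the genome was mm9 and edgeR was used. The aligner and the counting program are not given in the sources used here. The table held 28644 transcript rows for 22869 gene symbols. For 21988 symbols the row marked in the table was used, for 881 without a mark the row with most counts, and 3705 symbols had more than 1 row. For 945 symbols the row used was not the one with most counts. Gene names, membership of the X and Y chromosomes and transcript lengths came from GENCODE vM21 on GRCm38, which is not the assembly of the counts, so no coordinates are given. Of the genes, 22428 matched by accession, 284 by symbol and 157 not at all, and 22232 had a length.

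Groups were sex by title and stage, with treatment at P60. Title and sex characteristic disagreed for 10 libraries, and the title was kept because its replicate numbers run without a gap within each sex. Xist and the Y-linked genes followed the title in 59 of 60. No library was left out of the main analysis. The E18, P4, P14 and P60 saline libraries were fitted together (47 libraries in 8 groups) and the P60 saline and LPS libraries together (25 libraries in 4 groups). Genes were filtered by the edgeR default for the groups, scaled by TMM and tested by quasi-likelihood F tests with robust estimation in edgeR 4.0.16, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Sex comparisons are male over female. The stage comparisons and the LPS comparison of both sexes average the sexes with equal weight. The test of sex by age has 3 degrees of freedom, and that of sex by LPS is the LPS effect in males minus that in females.

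Gene lists, comparisons, the main method and a set of alternatives were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 at a fixed correlation between genes of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a list change at all, without comparing them to other genes. A list needed 3 tested members. Adjusted over the list alone means Benjamini-Hochberg over the members of that list. Camera calls that held with an estimated correlation were cell division and DNA replication at P14 against P4 and at P60 against P14, the interferon and lymphocyte lists at P60 against P14, and, by sex, the Y-linked list at every stage but in no test of sex by LPS, the X list up to P60 with saline, and border macrophage markers at P4. With LPS they were the inflammatory, NF-kB, interferon, glucocorticoid, neutrophil and monocyte lists in the mean of the sexes, the interferon and glucocorticoid lists in females, and these and the inflammatory list in males.

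Named genes follow a rule fixed in advance. They are the 6 largest rises and 6 largest falls with a mean of at least 10.0 CPM in a compared group, for each list up to 4 members with the smallest p in the direction of the list and up to 2 against it, and in sex comparisons the 10 genes of smallest p with the sex-linked genes. The 13 genes of the sex by LPS comparison plotted for both sexes, Ddx3y, and the genes called at E18 and in LPS libraries outside this rule, were chosen after their values were seen. Some genes that the rule names are not reported here. The developmental index used genes with at least a 2-fold change between its end stages, log2 CPM with a prior count of 2, and exact permutations, or 100000 resamples at P14.

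Replicate numbers were taken from the titles. At P4 libraries of one number shared a date and in 4 of 4 cases were the best match of each other, so a paired test is given there. At P14 libraries of one number shared a date in 10 of 10 cases, but a date held several numbers, and they correlated by 0.257 on average, against -0.0288 for other numbers. Libraries of one number correlated by 0.15 to 0.47 between P4 and E18 females, with 2 of 3 best matches, and over 0.1 in 4 of 5 cases between the sexes at P60 with saline, with 1 best match. Elsewhere at most 2 libraries had their own number as the best match. The labels do not say that numbers pair, and fits with the replicate number as a block were made for all comparisons. No library was a copy of another, with a chi-square per gene of 2.04 to 109 over 178 pairs within groups. Alternatives were DESeq2 1.42.0, limma-voom with sample weights, other scalings, filters, transcript rows, sex labels, blocks and single libraries left out. Those added after seeing the data were the choice of transcript row, the other scalings for the list tests, choroid plexus and endothelial scores as covariates, index genes not tied to these scores, thinning, the date block for sex by age, sex by LPS and the list tests, and leaving out libraries by Ttr or date.

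Precision differed with expression level and comparison. The median SE of a log2 fold was 0.20 for genes of at least 50 CPM and 0.47 under 5 CPM for P4 against E18, and 0.29 and 0.66 for sex at E18. Methods were tested on simulated data with 200 changed genes, where 2-fold changes were recovered for 64.2% of genes for P4 against E18, 82.1% for P14 against P4 and 91.0% for P60 against P14. By sex the recovery at 2-fold was 20.9% at E18, 31.3% at P4, 73.1% at P14, 50.7% at P60 with saline and 52.2% with LPS. For LPS it was 74.6% in the mean of the sexes, 43.3% in females and 49.3% in males, and it was 10.4% for sex by LPS and 17.9% for sex by age. At 4-fold it was 97.0% for P4 against E18, 69.7% for sex at E18 and 66.7% for sex by LPS. A ribosomal list raised 1.5-fold gave a camera adjusted p of 2.01e-32, with 0 of 28 other lists called by camera. The simulated genes varied independently of each other, so false list calls from genes that vary together were not tested. The recovery rates hold for such independent genes only. R was 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.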

Results

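Messenger RNA of mouse microglia, the resident immune cells of the brain, was sequenced in 60 libraries from C57BL/6N animals. The series covers a developmental time course and a challenge with lipopolysaccharide (LPS, a bacterial cell wall component that activates innate immune receptors) at postnatal day 60. By sample title there were 3 female and 4 male libraries at embryonic day 18 (E18), and 4 of each sex at postnatal day 4 (P4). There were 10 of each sex at P14, 7 female and 5 male saline libraries at P60, and 6 female and 7 male LPS libraries at P60. Total counts per library ran from 802016 to 3497454 with a median of 1907007.5. At P60 the median total was 974197 in females and 2376054 in males given saline, and 1062294 and 912229 with LPS. At P14 it was 2296745 in females and 1140656.5 in males. Changes below are log2 fold changes ± SE from edgeR, and levels are CPM (counts scaled to a library total of 1e6) ± SD. Tests are two-sided and adjusted p-values are Benjamini-Hochberg. They measure only the spread between these libraries, because the labels do not say that each library came from a separate animal. No collection date held libraries of 2 stages, or both saline and LPS libraries, so stage and treatment cannot be told apart from date.

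The sex-linked genes served as a check of the labels. Xist, the RNA that silences one X chromosome in female cells, ran from 1091 to 3848 CPM in the 30 libraries titled female and from 2.13 to 132 CPM in the 30 titled male. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 0 to 106 counts in libraries titled female, and 0 to 1775 in those titled male. Title and sex characteristic disagreed for 10 libraries, of which 4 were titled female and 6 male. Sex was taken from the title, and sex-linked genes followed it in 59 of the 60. The exception was the library labelled M_E18 4, with 0 Y-linked counts and 132 CPM of Xist, which its characteristic calls female. A count of 0 among its 1369084 counts allows up to 3, for counting error only.

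**Figure D1:**
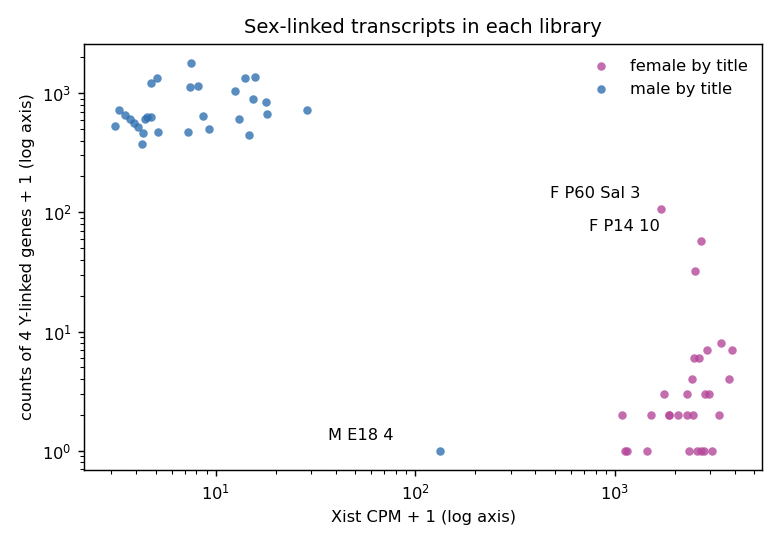
Xist level (CPM + 1, log axis) against summed counts of 4 Y-linked genes (+ 1, log axis), with 1 point per library coloured by the sex in its title. The libraries titled male lie at up to 132 CPM of Xist, and the library labelled M_E18 4 has 0 Y-linked counts.

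From E18 to P4, genes of mature microglial identity rose while transcripts of neurons and red blood cells fell (7 libraries against 8). The purinergic receptor P2ry12, which senses nucleotides released by damaged cells, rose by 2.49 ± 0.23 on the log2 scale, from 278 ± 114 to 1244 ± 244 CPM in females. Its relative P2ry13 rose by 2.73 ± 0.25. The proliferation marker Mki67 rose by 1.83 ± 0.33, and Il1b, the gene of the inflammatory cytokine interleukin-1 beta, by 2.25 ± 0.28. The neuronal tubulin Tubb3 fell by 5.29 ± 0.48. No fit adjusted for neuron or red blood cell transcripts, so the rises at this step cannot be told apart from a falling share of other cells. In all, 3535 genes rose and 3151 fell of 13853 tested, and 1545 of the rises and 1648 of the falls were at least 2-fold. DESeq2 size factors moved the median of all genes from 0.03 to -0.10.

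Among lists fixed before the data were examined, the homeostatic microglia genes gave the clearest rise: 27 of 30 rose, 0 fell and 3 did not pass (adjusted over the list alone 27 rose and 0 fell, camera adjusted p = 2.81e-15, adjusted p = 0.209 with an estimated correlation). In the cell division list 20 of 30 rose, 0 fell and 10 did not pass (adjusted over the list alone 20 rose and 0 fell, camera adjusted p = 2.33e-04, adjusted p = 0.431 with an estimated correlation). Kif11, a spindle motor, was at 1.21 ± 0.20 and Anln at 1.57 ± 0.26. In the DNA replication list 5 of 30 rose, 2 fell and 23 did not pass (adjusted over the list alone 3 rose and 1 fell, camera adjusted p = 0.545), the helicase subunits splitting between Mcm4 at 0.72 ± 0.15 and Mcm7 at -0.73 ± 0.24. Of the immature and amoeboid genes, 12 of 25 rose, 4 fell and 9 did not pass (adjusted over the list alone 13 rose and 4 fell, camera adjusted p = 0.315). Itgax was at 1.74 ± 0.28 and Lpl, a lipoprotein lipase, at 1.60 ± 0.27, against Fabp5 at -1.42 ± 0.28. Of the inflammatory cytokines and chemokines, 15 of 20 rose, 1 fell and 4 did not pass (adjusted over the list alone 16 rose and 1 fell, camera adjusted p = 1.48e-05, adjusted p = 0.209 with an estimated correlation). Il1a rose by 2.46 ± 0.30 and the chemokine Ccl3 by 2.05 ± 0.25, while Ccl5 fell by 3.35 ± 0.69. Of the NF-kB feedback and TLR signalling genes, 23 of 26 rose, 0 fell and 3 did not pass (adjusted over the list alone 24 rose and 0 fell, camera adjusted p = 5.49e-09, adjusted p = 0.209 with an estimated correlation). The pattern receptors Tlr2 and Tlr4 rose by 1.79 ± 0.20 and 1.53 ± 0.20.

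Phagocytic and Fc receptors also moved together: 16 of 20 rose, 0 fell and 4 did not pass (adjusted over the list alone 17 rose and 0 fell, camera adjusted p = 1.57e-05, adjusted p = 0.209 with an estimated correlation). Mertk, a receptor for apoptotic cells, was at 2.18 ± 0.28 and Fcgr1 at 1.66 ± 0.22. Of the complement genes, 10 of 16 rose, 1 fell and 5 did not pass (adjusted over the list alone 11 rose and 1 fell, camera adjusted p = 2.12e-04, adjusted p = 0.209 with an estimated correlation). Itgam was at 2.02 ± 0.26. Of the lysosomal genes, 18 of 28 rose, 0 fell and 10 did not pass (adjusted over the list alone 18 rose and 0 fell, camera adjusted p = 8.84e-05, adjusted p = 0.457 with an estimated correlation). Of the MHC class I genes, 8 of 17 rose, 1 fell and 8 did not pass (adjusted over the list alone 9 rose and 1 fell, camera adjusted p = 0.00567, adjusted p = 0.431 with an estimated correlation). Of the class II genes, 6 of 9 rose, 0 fell and 3 did not pass (adjusted over the list alone 6 rose and 0 fell, camera adjusted p = 0.0357, adjusted p = 0.431 with an estimated correlation). Of the immediate early genes, 19 of 23 rose, 0 fell and 4 did not pass (adjusted over the list alone 20 rose and 0 fell, camera adjusted p = 1.57e-05, adjusted p = 0.431 with an estimated correlation). Egr2 was at 1.77 ± 0.32. For the type I interferon response the median was 0.04: 12 of 35 rose, 1 fell and 22 did not pass (adjusted over the list alone 12 rose and 1 fell, camera adjusted p = 0.232). Isg15 fell by 1.08 ± 0.35. Of the heat shock genes 5 of 14 rose, 1 fell and 8 did not pass (adjusted over the list alone 5 rose and 1 fell, camera adjusted p = 0.375). Of the glucocorticoid-induced genes 2 of 15 rose, 1 fell and 12 did not pass (adjusted over the list alone 2 rose and 1 fell, camera adjusted p = 0.641).

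Ribosomal, respiratory and metabolic lists went down. Of the cytosolic ribosomal proteins, 0 of 44 rose, 30 fell and 14 did not pass (adjusted over the list alone 0 rose and 34 fell, camera adjusted p = 2.05e-06, adjusted p = 0.431 with an estimated correlation). Rpl22 was at -1.15 ± 0.20 and Rps14 at -1.33 ± 0.27. Of the oxidative phosphorylation genes, 0 of 41 rose, 31 fell and 10 did not pass (adjusted over the list alone 0 rose and 35 fell, camera adjusted p = 1.48e-05, adjusted p = 0.574 with an estimated correlation). Sdhb was at -0.96 ± 0.21. Of the cholesterol synthesis genes, 0 of 19 rose, 15 fell and 4 did not pass (adjusted over the list alone 0 rose and 15 fell, camera adjusted p = 3.79e-04, adjusted p = 0.264 with an estimated correlation). Fdps was at -1.48 ± 0.36. Of the glycolysis genes, 3 of 18 rose, 11 fell and 4 did not pass (adjusted over the list alone 3 rose and 11 fell, camera adjusted p = 0.0208, adjusted p = 0.431 with an estimated correlation), where Ldha fell by 1.32 ± 0.23 and Hk2 rose by 1.60 ± 0.32. The E18 libraries titled male held 23.4% ± 15.3 (SD, n = 4) of their counts in transcripts of at most 1500 bases, with 45.1% in the library labelled M_E18 4. Those titled female held 12.2% ± 1.91 (SD, n = 3). Without the libraries in which the choroid plexus transcript Ttr took over 10% of the counts, the median of the ribosomal list went from -0.79 to -0.58 with 24 falls, and that of oxidative phosphorylation from -0.81 to -0.41 with 10 falls. Cell division then had 12 rises and a median of 0.56.

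Markers of other cells changed at the same step. Of the neuron markers, 0 of 17 rose, 17 fell and 0 did not pass (adjusted over the list alone 0 rose and 17 fell, camera adjusted p = 1.56e-12, adjusted p = 0.209 with an estimated correlation). Of the red blood cell markers, 0 of 6 rose, 6 fell and 0 did not pass (adjusted over the list alone 0 rose and 6 fell, camera adjusted p = 0.00551, adjusted p = 0.431 with an estimated correlation). The embryonic globin Hbb-y was at -3.32 ± 0.65. Of the neutrophil markers, 9 of 13 rose, 0 fell and 4 did not pass (adjusted over the list alone 9 rose and 0 fell, camera adjusted p = 0.024, adjusted p = 0.519 with an estimated correlation). Mpo, the myeloperoxidase, was at 4.54 ± 1.00. Of the monocyte markers, 6 of 11 rose, 0 fell and 5 did not pass (adjusted over the list alone 6 rose and 1 fell, camera adjusted p = 0.115). Ccr2 was at 1.62 ± 0.33. Of the astrocyte markers 4 of 13 rose, 0 fell and 9 did not pass (adjusted over the list alone 3 rose and 0 fell, camera adjusted p = 0.516). Of the oligodendrocyte lineage markers 3 of 14 rose, 0 fell and 11 did not pass (adjusted over the list alone 2 rose and 0 fell, camera adjusted p = 0.583). Of the endothelial and pericyte markers 3 of 15 rose, 0 fell and 12 did not pass (adjusted over the list alone 3 rose and 0 fell, camera adjusted p = 0.32). Border macrophage markers had a median of 0.05 against a downward test: 2 of 11 rose, 2 fell and 7 did not pass (adjusted over the list alone 2 rose and 2 fell, camera adjusted p = 0.545). Pf4 was at -1.62 ± 0.40. Lymphocyte markers had a median of 0.12, also against a downward test: 2 of 6 rose, 1 fell and 3 did not pass (adjusted over the list alone 2 rose and 1 fell, camera adjusted p = 0.904). Choroid plexus and ependymal markers had a median of -0.27 and an upward test: 4 of 9 rose, 0 fell and 5 did not pass (adjusted over the list alone 3 rose and 0 fell, camera adjusted p = 0.365), where the ependymal Tmem212 rose by 3.64 ± 0.68. Of the Y-linked genes, 0 of 4 rose, 0 fell and 4 did not pass (adjusted over the list alone 0 rose and 0 fell, camera adjusted p = 0.32). Of the X inactivation and escape genes, 4 of 10 rose, 0 fell and 6 did not pass (adjusted over the list alone 3 rose and 0 fell, camera adjusted p = 0.45). With an estimated correlation none of the 17 lists camera called passed.

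Between P4 and P14, the homeostatic genes rose further and proliferation fell (8 libraries against 20). Tmem119, a microglial surface protein, rose by 2.82 ± 0.28, from 104 ± 18.4 to 655 ± 259.6 CPM in females and from 122 ± 41.9 to 632 ± 239 CPM in males. Selplg, a ligand of selectins, rose by 3.16 ± 0.25 and P2ry12 by 1.98 ± 0.19. Spp1, or osteopontin, fell by 4.65 ± 0.23, and the lysosomal glycoprotein Gpnmb by 3.80 ± 0.28. The growth factor Igf1 fell by 2.11 ± 0.16. In all, 2856 genes rose and 2888 fell, with 718 and 1595 at least 2-fold.

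Of the homeostatic genes, 30 of 30 rose, 0 fell and 0 did not pass (adjusted over the list alone 30 rose and 0 fell, camera adjusted p = 1.92e-26, adjusted p = 0.0523 with an estimated correlation). Of the immature and amoeboid genes, 2 of 25 rose, 17 fell and 6 did not pass (adjusted over the list alone 2 rose and 18 fell, camera adjusted p = 4.75e-06, adjusted p = 0.0786 with an estimated correlation). Itgax was at -2.60 ± 0.21. Of the cell division genes, 0 of 30 rose, 30 fell and 0 did not pass (adjusted over the list alone 0 rose and 30 fell, camera adjusted p = 1.51e-24, adjusted p = 0.0123 with an estimated correlation). The DNA topoisomerase Top2a was at -1.94 ± 0.18 and Aurka at -2.11 ± 0.19. Of the DNA replication genes, 0 of 30 rose, 28 fell and 2 did not pass (adjusted over the list alone 1 rose and 28 fell, camera adjusted p = 1.18e-19, adjusted p = 0.00122 with an estimated correlation). Mcm4 was at -1.68 ± 0.12 and Uhrf1 at -2.06 ± 0.17. Of the MHC class II genes, 8 of 9 rose, 0 fell and 1 did not pass (adjusted over the list alone 8 rose and 0 fell, camera adjusted p = 2.77e-05, adjusted p = 0.0786 with an estimated correlation). H2-DMa was at 1.59 ± 0.16 and H2-Eb1 at 1.47 ± 0.26. Of the class I genes, 10 of 17 rose, 0 fell and 7 did not pass (adjusted over the list alone 11 rose and 0 fell, camera adjusted p = 4.74e-04, adjusted p = 0.301 with an estimated correlation). Of the heat shock genes, 14 of 14 rose, 0 fell and 0 did not pass (adjusted over the list alone 14 rose and 0 fell, camera adjusted p = 2.11e-09, adjusted p = 0.0805 with an estimated correlation). Hspb1 was at 2.40 ± 0.31. Of the glucocorticoid-induced genes, 10 of 15 rose, 1 fell and 4 did not pass (adjusted over the list alone 10 rose and 1 fell, camera adjusted p = 2.85e-04, adjusted p = 0.0643 with an estimated correlation). The kinase Sgk1 was at 2.35 ± 0.20 and the clock gene Per1 at 1.83 ± 0.25. Of the immediate early genes, 14 of 23 rose, 1 fell and 8 did not pass (adjusted over the list alone 15 rose and 1 fell, camera adjusted p = 8.57e-06, adjusted p = 0.335 with an estimated correlation). Atf3 was at 2.02 ± 0.21.

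Of the NF-kB feedback and TLR signalling genes, 13 of 26 rose, 3 fell and 10 did not pass (adjusted over the list alone 13 rose and 3 fell, camera adjusted p = 9.31e-04, adjusted p = 0.402 with an estimated correlation). Relb was at 1.21 ± 0.22. The complement genes split, with C1qa at 1.05 ± 0.22 and C1qb at 0.94 ± 0.19 against C3 at -2.83 ± 0.30 (camera adjusted p = 0.459). So did the phagocytic receptors, with Trem2 at 0.90 ± 0.21 against the scavenger receptor Marco at -4.79 ± 0.53 (camera adjusted p = 0.589). Of the cholesterol synthesis genes, 0 of 19 rose, 8 fell and 11 did not pass (adjusted over the list alone 0 rose and 8 fell, camera adjusted p = 0.0252, adjusted p = 0.402 with an estimated correlation). No ribosomal or oxidative phosphorylation gene of the lists passed the edgeR test, which called 6746 of all genes at an unadjusted p under 0.05. Of the astrocyte markers, 0 of 13 rose, 11 fell and 2 did not pass (adjusted over the list alone 0 rose and 11 fell, camera adjusted p = 3.51e-06, adjusted p = 0.233 with an estimated correlation). The radial glial fatty acid binder Fabp7 was at -4.02 ± 0.35. Of the neuron markers, 0 of 17 rose, 10 fell and 7 did not pass (adjusted over the list alone 0 rose and 10 fell, camera adjusted p = 0.00134, adjusted p = 0.402 with an estimated correlation). Of the neutrophil markers, 1 of 13 rose, 11 fell and 1 did not pass (adjusted over the list alone 1 rose and 11 fell, camera adjusted p = 0.00134, adjusted p = 0.335 with an estimated correlation). The antimicrobial Camp was at -3.49 ± 0.54. Of the monocyte markers, 0 of 11 rose, 7 fell and 4 did not pass (adjusted over the list alone 0 rose and 7 fell, camera adjusted p = 0.00691, adjusted p = 0.233 with an estimated correlation). Of the red blood cell markers, 0 of 6 rose, 5 fell and 1 did not pass (adjusted over the list alone 0 rose and 5 fell, camera adjusted p = 0.00256, adjusted p = 0.325 with an estimated correlation). The myelin gene Mbp rose by 2.12 ± 0.57, in a list without a call as a whole (camera adjusted p = 0.334). Rises were 49.7% of called genes. Scaled by total count alone there were 1376 rises and 5175 falls, and the median of all genes moved from -0.01 to -0.30. With DESeq2 size factors rises were 37.5% of the calls, at a median of -0.12.

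**Figure D2:**
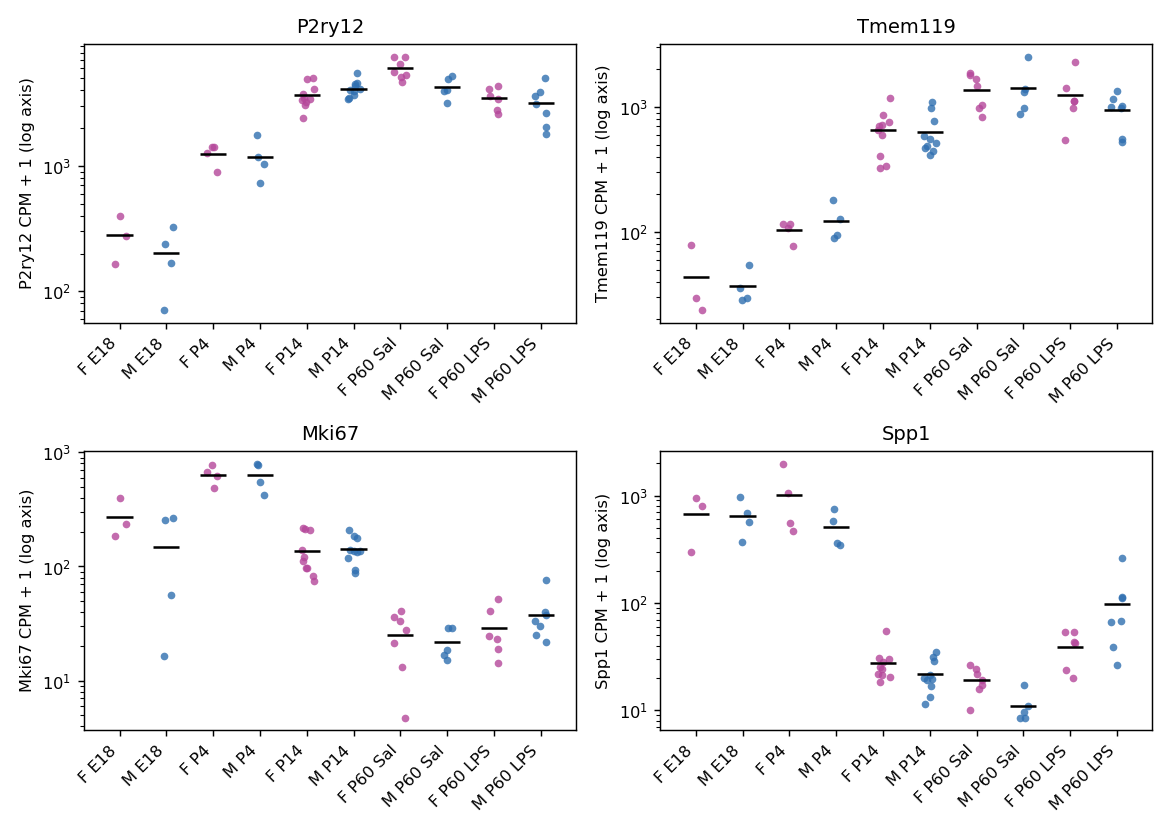
Levels (CPM + 1, log axis) of P2ry12, Tmem119, Mki67 and Spp1 in each group, with 1 point per library and a bar at the group mean. P2ry12 goes from 278 CPM in females at E18 to 5990 CPM in females given saline at P60, while Spp1 falls between P4 and P14.

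From P14 to adulthood, proliferation genes fell further, and interferon, MHC class II and cytotoxic lymphocyte genes rose (20 libraries against 12). Mki67 went from 135 ± 55.8 to 24.3 ± 13 CPM in females and from 140.5 ± 38.5 to 20.7 ± 6.64 CPM in males. Top2a fell by 2.36 ± 0.20 and the replication factor Cdt1 by 2.16 ± 0.25. The interferon-induced Ifit3 rose by 2.05 ± 0.27, the MHC class II H2-Aa by 1.53 ± 0.23, and the cytotoxic Gzmb by 3.19 ± 0.42. The B cell survival factor Tnfsf13b rose by 3.53 ± 0.29. In all, 2557 genes rose and 3558 fell, with 629 and 1389 at least 2-fold.

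Of the cell division genes, 0 of 30 rose, 30 fell and 0 did not pass (adjusted over the list alone 0 rose and 30 fell, camera adjusted p = 3.51e-25, adjusted p = 0.02 with an estimated correlation). Of the DNA replication genes, 0 of 30 rose, 25 fell and 5 did not pass (adjusted over the list alone 0 rose and 25 fell, camera adjusted p = 5.86e-08, adjusted p = 0.0481 with an estimated correlation). Of the type I interferon genes, 22 of 35 rose, 0 fell and 13 did not pass (adjusted over the list alone 22 rose and 0 fell, camera adjusted p = 4.68e-08, adjusted p = 0.0481 with an estimated correlation). Ifit1 was at 1.85 ± 0.29. Of the MHC class II genes, 6 of 9 rose, 1 fell and 2 did not pass (adjusted over the list alone 6 rose and 1 fell, camera adjusted p = 0.0024, adjusted p = 0.344 with an estimated correlation), the exception being Cd40 at -1.21 ± 0.37. Of the class I genes, 7 of 17 rose, 2 fell and 8 did not pass (adjusted over the list alone 8 rose and 2 fell, camera adjusted p = 0.0311, adjusted p = 0.794 with an estimated correlation). Of the homeostatic genes, 15 of 30 rose, 4 fell and 11 did not pass (adjusted over the list alone 16 rose and 5 fell, camera adjusted p = 0.00251, adjusted p = 0.794 with an estimated correlation). Tmem119 was at 1.10 ± 0.20 and the fructose transporter Slc2a5 at 1.17 ± 0.16 against Sparc at -0.70 ± 0.11. Of the immature and amoeboid genes, 4 of 25 rose, 14 fell and 7 did not pass (adjusted over the list alone 4 rose and 14 fell, camera adjusted p = 0.0129, adjusted p = 0.601 with an estimated correlation). Lpl was at -2.77 ± 0.21 and the filament protein Vim at -1.54 ± 0.17. Of the cholesterol synthesis genes, 1 of 19 rose, 10 fell and 8 did not pass (adjusted over the list alone 2 rose and 12 fell, camera adjusted p = 0.0024, adjusted p = 0.439 with an estimated correlation). Insig1 was at -1.40 ± 0.13.

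Of the cytosolic ribosomal proteins, 0 of 44 rose, 29 fell and 15 did not pass (adjusted over the list alone 1 rose and 33 fell, camera adjusted p = 4.01e-05, adjusted p = 0.794 with an estimated correlation). Of the oxidative phosphorylation genes, 9 of 41 rose, 0 fell and 32 did not pass (adjusted over the list alone 8 rose and 0 fell, camera adjusted p = 0.00461, adjusted p = 0.826 with an estimated correlation). NF-kB genes split without a call, with Relb at -1.77 ± 0.20 and Nfkb2 at -1.88 ± 0.25 against Tlr4 at 0.81 ± 0.13 (camera adjusted p = 0.34). Of the lymphocyte markers, 4 of 6 rose, 0 fell and 2 did not pass (adjusted over the list alone 4 rose and 0 fell, camera adjusted p = 0.0024, adjusted p = 0.0481 with an estimated correlation). Gzma was at 2.35 ± 0.48 and Klrd1, a natural killer cell receptor, at 2.08 ± 0.35. Of the neuron markers, 0 of 17 rose, 10 fell and 7 did not pass (adjusted over the list alone 0 rose and 10 fell, camera adjusted p = 0.0235, adjusted p = 0.794 with an estimated correlation). Of the astrocyte markers, 1 of 13 rose, 8 fell and 4 did not pass (adjusted over the list alone 2 rose and 8 fell, camera adjusted p = 0.0338, adjusted p = 0.794 with an estimated correlation). Slc1a2 was at -3.34 ± 0.45. The choroid plexus genes Kl and Enpp2 rose by 2.25 ± 0.38 and 1.53 ± 0.41, in a list without a call (camera adjusted p = 0.617), and the pericyte gene Rgs5 fell by 1.61 ± 0.24 (camera adjusted p = 0.0853).

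The title of the series names sex differences, and males were compared with females at each stage, with positive values higher in males. At E18, 7 genes were higher and 3 lower in libraries titled male (4, against 3 titled female). The 4 include the library labelled M_E18 4, which has no Y-linked counts, and without it 6 genes were called. The Y-linked Kdm5d and Uty were higher by 8.79 ± 1.06 and 6.55 ± 0.84, and Eif2s3y and Ddx3y by 7.56 ± 1.22 and 7.24 ± 1.22. Xist and its antisense Tsix were at -5.20 ± 0.71 and -6.34 ± 0.51, and the X-linked histone demethylase Kdm6a, which escapes X inactivation, at -1.37 ± 0.29. The autosomal genes were Ech1, a peroxisomal and mitochondrial enzyme of fatty acid oxidation, at 1.75 ± 0.37, adjusted p = 0.0388, Ssr2 at 1.65 ± 0.36, adjusted p = 0.0427, and Rnf5 at 1.25 ± 0.26, adjusted p = 0.0333. No ribosomal or respiratory gene passed over all genes, where edgeR called 2602 genes at an unadjusted p under 0.05, DESeq2 500 and limma-voom 1253 after adjustment. Adjusted over the list alone, 27 of 44 ribosomal genes were higher in males (camera adjusted p = 2.48e-14, adjusted p = 0.416 with an estimated correlation), and 38 of 41 oxidative phosphorylation genes (camera adjusted p = 5.17e-16, adjusted p = 0.51 with an estimated correlation). Glycolysis had 8 of 18 (camera adjusted p = 0.00317, adjusted p = 0.51 with an estimated correlation) and the lysosomal genes 3 of 28 (camera adjusted p = 0.0103, adjusted p = 0.858 with an estimated correlation).

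Without the libraries with over 10% Ttr, which included the libraries labelled M_E18 3 and M_E18 4, the calls were the 6 genes Xist, Tsix and the 4 Y-linked ones. The median of the ribosomal list went from 1.02 to 0.43 and that of oxidative phosphorylation from 1.22 to 0.21, and that of the lysosomal list turned from 0.37 to -0.15. With collection date as a block 5 genes were called, and the medians were 0.31 for the ribosomal list, 0.05 for oxidative phosphorylation (camera adjusted p = 0.906) and 0.03 for glycolysis (camera adjusted p = 0.942). Leaving out the library labelled M_E18 1 gave 823 genes, M_E18 2 gave 2475 and F_P60_Sal 6 gave 97. It gave 6 without F_E18 1 or F_E18 3. Either other scaling gave 4 higher and 3 lower genes.

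At P4, P14 and P60 with saline, the same 6 genes passed each time: Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty. At P4 (4 libraries of each sex) Xist was at -7.97 ± 0.78 and Kdm5d at 9.21 ± 0.93. Of 13853 tested genes, 46 had an unadjusted p under 0.05, a share far below the 0.05 that chance alone gives. This test did not pair the libraries, and female and male libraries of one number correlated by 0.458 on average. Why the count was so low was not tested. The replicate numbers paired female and male libraries of one date at P4, and a paired test also called 6 genes. Border macrophage markers were the one list outside the sex chromosomes that held with an estimated correlation, at a median of -0.88 (camera adjusted p = 1.47e-09, adjusted p = 0.0279 with an estimated correlation). No member passed by edgeR, DESeq2 or limma-voom, among 46 of all genes at an unadjusted p under 0.05, and fry, a rotation test of the whole list, gave an adjusted p of 0.907. Its members include Cd163, a haemoglobin scavenger receptor, at -1.45 ± 0.51, adjusted p = 1, and Lyve1 at -1.21 ± 0.55, adjusted p = 1. Immature and amoeboid genes had a median of -0.22 (camera adjusted p = 1.10e-05, adjusted p = 0.111 with an estimated correlation), with Spp1 at 1007 ± 691 CPM in females and 509 ± 193 CPM in males. These list tests did not pair the libraries. By pair, the mean level of the immature list in male and female was 6.20 and 6.30, 6.80 and 6.95, 6.47 and 6.64, and 6.69 and 7.32 log2 CPM.

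At P14 (10 of each sex) Xist was at -8.88 ± 0.53 and Uty at 8.04 ± 0.47. Of 13853 tested genes, 655 had an unadjusted p under 0.05, a share just below the 0.05 that chance alone gives. The count is thus no sign of sex differences beyond the called genes. Kdm6a was at -0.68 ± 0.17, adjusted p = 0.352. Choroid plexus and ependymal markers were lower in males, with a median of -0.88 (camera adjusted p = 1.10e-04, adjusted p = 0.473 with an estimated correlation), and Ttr took 2.99% ± 1.96 (SD, n = 10) of counts in females and 1.48% ± 1.01 (SD, n = 10) in males. Beside it, oxidative phosphorylation had a median of -0.24 (camera adjusted p = 1.10e-04, adjusted p = 0.852 with an estimated correlation) and glycolysis of -0.32 (camera adjusted p = 3.52e-04, adjusted p = 0.433 with an estimated correlation). With a choroid plexus score as covariate, the oxidative phosphorylation list and the homeostatic list (camera adjusted p = 0.0222, adjusted p = 0.852 with an estimated correlation) turned direction and lost their calls. Within collection dates 7 genes passed at P14.

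At P60 with saline (7 female and 5 male libraries), Xist was at -7.72 ± 0.69 and Kdm5d at 6.45 ± 0.66, and 1340 genes had an unadjusted p under 0.05. Camera called 17 lists lower and 3 higher in males, and with an estimated correlation only the Y-linked list and the X inactivation and escape list passed. The interferon list had a median of -0.48 (camera adjusted p = 4.89e-07, adjusted p = 0.115 with an estimated correlation), with Ifit2 at -1.55 ± 0.35, adjusted p = 0.0903. The libraries labelled F_P60_Sal 5 and F_P60_Sal 6 stood apart on this list, at 5.24 and 4.89 log2 CPM. The other saline females lay at 4.17 to 4.47 and the saline males at 3.94 to 4.31. Inflammatory genes had a median of -0.49 (camera adjusted p = 2.09e-05, adjusted p = 0.257 with an estimated correlation), with Ccl3 at -0.49 ± 0.27, adjusted p = 0.562, and heat shock genes of -0.46 (camera adjusted p = 1.65e-06, adjusted p = 0.257 with an estimated correlation). Homeostatic genes had a median of -0.19 (camera adjusted p = 1.62e-05, adjusted p = 0.438 with an estimated correlation), with P2ry12 at -0.52 ± 0.24, adjusted p = 0.487. Endothelial and pericyte markers were on the other side, with a median of 0.47 (camera adjusted p = 3.14e-05, adjusted p = 0.286 with an estimated correlation) and Cldn5, a tight junction protein of brain vessels, at 0.98 ± 0.40, adjusted p = 0.416. With choroid plexus and endothelial scores as covariates, the homeostatic, NF-kB and complement lists turned direction without a call. With collection date as a block 11 genes passed, DESeq2 called 26 and limma-voom 184, and without the library labelled F_P60_Sal 7 edgeR called 35.

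The test of whether the sex difference changed between the 4 stages called 0 genes with edgeR, 0 with DESeq2 and 743 with limma-voom, and 1723 genes had an unadjusted p under 0.05 in edgeR. Without the library labelled M_E18 2 edgeR called 486. At this depth and number a 2-fold change in the sex difference was recovered for 17.9% of simulated genes, so most changes of that size would be missed.

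LPS at P60 raised inflammatory, interferon and NF-kB genes in the mean of both sexes (13 LPS and 12 saline libraries). Saa3, an acute-phase serum amyloid protein, rose by 8.73 ± 0.80, the endothelial adhesion molecule Selp by 8.20 ± 0.43, and Csf3, the granulocyte growth factor, by 7.97 ± 0.57. Lcn2, an iron-binding antibacterial protein, rose by 6.51 ± 0.56 and Il1rn, the interleukin-1 receptor antagonist, by 5.98 ± 0.40. The endothelial genes Clec14a, Egfl7 and Cldn5 fell by 3.76 ± 0.33, 3.32 ± 0.32 and 3.14 ± 0.35. In all, 1102 genes rose and 416 fell of 10538 tested. Scaled by total count alone, rises made up 53.7% of the calls, against 72.6%, and the median of all genes moved from -0.07 to -0.15.

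Of the inflammatory cytokines and chemokines, 22 of 23 rose, 0 fell and 1 did not pass (adjusted over the list alone 23 rose and 0 fell, camera adjusted p = 3.87e-30, adjusted p = 0.00717 with an estimated correlation). Cxcl10 was at 3.92 ± 0.31 and the prostaglandin synthase Ptgs2 at 3.47 ± 0.29. Of the type I interferon genes, 33 of 35 rose, 0 fell and 2 did not pass (adjusted over the list alone 33 rose and 0 fell, camera adjusted p = 8.71e-52, adjusted p = 0.00467 with an estimated correlation). Gbp2 was at 4.16 ± 0.24 and Ifit1 at 5.22 ± 0.36. Of the NF-kB feedback and TLR signalling genes, 22 of 26 rose, 0 fell and 4 did not pass (adjusted over the list alone 23 rose and 0 fell, camera adjusted p = 2.63e-19, adjusted p = 0.0417 with an estimated correlation). Bcl3 was at 2.97 ± 0.33 and Irak3 at 2.97 ± 0.32. Of the glucocorticoid-induced genes, 9 of 14 rose, 0 fell and 5 did not pass (adjusted over the list alone 11 rose and 0 fell, camera adjusted p = 1.15e-10, adjusted p = 0.00467 with an estimated correlation). The metallothionein Mt2 was at 4.58 ± 0.39 and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 2.31 ± 0.23. Of the MHC class I genes, 9 of 17 rose, 0 fell and 8 did not pass (adjusted over the list alone 9 rose and 0 fell, camera adjusted p = 1.07e-05, adjusted p = 0.174 with an estimated correlation). Of the complement genes, 4 of 15 rose, 0 fell and 11 did not pass (adjusted over the list alone 5 rose and 0 fell, camera adjusted p = 4.37e-04, adjusted p = 0.175 with an estimated correlation). C3 was at 3.46 ± 0.35 and Cfb at 3.03 ± 0.31. Of the immediate early genes, 6 of 23 rose, 0 fell and 17 did not pass (adjusted over the list alone 8 rose and 0 fell, camera adjusted p = 3.77e-04, adjusted p = 0.67 with an estimated correlation). Of the homeostatic genes, 0 of 30 rose, 5 fell and 25 did not pass (adjusted over the list alone 0 rose and 5 fell, camera adjusted p = 0.0117, adjusted p = 0.84 with an estimated correlation). Gpr34 was at -0.72 ± 0.18 and P2ry12 at -0.53 ± 0.15. The immature and amoeboid list was not called (camera adjusted p = 0.344), though Spp1 rose by 2.25 ± 0.29 and Csf1 by 1.27 ± 0.23.

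Markers of blood leukocytes rose at the same time. Of the neutrophil markers, 9 of 10 rose, 0 fell and 1 did not pass (adjusted over the list alone 9 rose and 0 fell, camera adjusted p = 3.94e-10, adjusted p = 0.0417 with an estimated correlation). S100a9 was at 3.28 ± 0.43 and the collagenase Mmp8 at 4.41 ± 0.53. Of the monocyte markers, 9 of 11 rose, 0 fell and 2 did not pass (adjusted over the list alone 9 rose and 0 fell, camera adjusted p = 7.15e-09, adjusted p = 0.0417 with an estimated correlation). Plac8 was at 3.79 ± 0.41 and Ms4a4c at 3.30 ± 0.37, while Ccr2 was at -0.29 ± 0.29, adjusted p = 0.567. Of the endothelial and pericyte markers, 1 of 14 rose, 5 fell and 8 did not pass (adjusted over the list alone 1 rose and 7 fell, camera adjusted p = 0.00456, adjusted p = 0.631 with an estimated correlation). Tek was at -1.61 ± 0.23 and, in the other direction, Cdh5 at 0.84 ± 0.18. The mean level of this list went from 5.97 ± 0.65 to 6.20 ± 0.38 log2 CPM (SD) in females and from 6.63 ± 0.37 to 5.46 ± 0.27 in males. Gzmb rose by 2.90 ± 0.35 and the gap junction gene Gja1 by 2.31 ± 0.32. Of the oxidative phosphorylation genes, 0 of 40 rose, 1 fell and 39 did not pass (adjusted over the list alone 0 rose and 0 fell, camera adjusted p = 0.00439, adjusted p = 0.841 with an estimated correlation). Without the 4 LPS libraries of 9 April, 1157 genes were called.

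Taken by sex, LPS raised 439 genes and lowered 94 in females (6 and 7 libraries), and raised 1256 and lowered 798 in males (7 and 5 libraries). In females Selp rose by 8.26 ± 0.57, Saa3 by 7.41 ± 1.12, Cxcl1 by 4.67 ± 0.50 and Lcn2 by 6.85 ± 0.74. P2ry12 fell by 0.77 ± 0.21 and Gpr34 by 0.95 ± 0.25. Of the female inflammatory genes, 12 of 23 rose, 0 fell and 11 did not pass (adjusted over the list alone 15 rose and 0 fell, camera adjusted p = 9.36e-18, adjusted p = 0.0649 with an estimated correlation). Of the interferon genes, 27 of 35 rose, 0 fell and 8 did not pass (adjusted over the list alone 32 rose and 0 fell, camera adjusted p = 5.52e-46, adjusted p = 0.00853 with an estimated correlation). The library labelled F_P60_LPS 3 stood apart on both lists. It was at 6.31 log2 CPM on the inflammatory list, against 7.08 to 7.95 in the other LPS females. On the interferon list it was at 5.25, against 6.42 to 7.44. Of the glucocorticoid-induced genes, 7 of 14 rose, 0 fell and 7 did not pass (adjusted over the list alone 11 rose and 0 fell, camera adjusted p = 7.38e-10, adjusted p = 0.00853 with an estimated correlation). Of the homeostatic genes, 0 of 30 rose, 4 fell and 26 did not pass (adjusted over the list alone 0 rose and 4 fell, camera adjusted p = 1.83e-05, adjusted p = 0.603 with an estimated correlation). Of the heat shock genes, 0 of 14 rose, 1 fell and 13 did not pass (adjusted over the list alone 0 rose and 2 fell, camera adjusted p = 8.52e-06, adjusted p = 0.272 with an estimated correlation). Hspe1 was at -1.07 ± 0.31. Blood leukocyte markers rose in the same libraries. Of the neutrophil markers, 6 of 10 rose, 0 fell and 4 did not pass (adjusted over the list alone 8 rose and 0 fell, camera adjusted p = 9.74e-08, adjusted p = 0.132 with an estimated correlation). Of the monocyte markers, 5 of 11 rose, 0 fell and 6 did not pass (adjusted over the list alone 7 rose and 0 fell, camera adjusted p = 4.10e-06, adjusted p = 0.163 with an estimated correlation).

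In males Saa3 rose by 10.05 ± 1.16, Csf3 by 8.89 ± 0.88, Spp1 by 3.40 ± 0.44 and Map3k8, a kinase downstream of TLR signals, by 2.88 ± 0.27. Cldn5 fell by 4.91 ± 0.54 and the angiogenic factor Egfl7 by 4.80 ± 0.48. Of the male inflammatory genes, 23 of 23 rose, 0 fell and 0 did not pass (adjusted over the list alone 23 rose and 0 fell, camera adjusted p = 1.24e-27, adjusted p = 0.0162 with an estimated correlation). Of the interferon genes, 32 of 35 rose, 0 fell and 3 did not pass (adjusted over the list alone 33 rose and 0 fell, camera adjusted p = 3.57e-40, adjusted p = 0.0162 with an estimated correlation). In the same libraries, of the neutrophil markers 8 of 10 rose, 0 fell and 2 did not pass (adjusted over the list alone 9 rose and 0 fell, camera adjusted p = 1.17e-07, adjusted p = 0.0956 with an estimated correlation), and of the monocyte markers 8 of 11 rose, 0 fell and 3 did not pass (adjusted over the list alone 8 rose and 0 fell, camera adjusted p = 6.72e-07, adjusted p = 0.0956 with an estimated correlation). The libraries labelled M_P60_LPS 3, 4 and 5 stood apart on the inflammatory list, at 8.74, 9.03 and 8.75 log2 CPM against 7.16 to 7.75 in the other males. Of the homeostatic genes 0 of 30 rose, 0 fell and 30 did not pass (adjusted over the list alone 0 rose and 0 fell, camera adjusted p = 0.603). Of the oxidative phosphorylation genes, 0 of 40 rose, 5 fell and 35 did not pass (adjusted over the list alone 0 rose and 4 fell, camera adjusted p = 6.14e-05, adjusted p = 0.643 with an estimated correlation). Of the endothelial and pericyte markers, 0 of 14 rose, 8 fell and 6 did not pass (adjusted over the list alone 0 rose and 9 fell, camera adjusted p = 3.38e-06, adjusted p = 0.204 with an estimated correlation).

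Between the sexes 359 genes rose in both, where 52.3 would by chance, and 27 fell in both, where 7.12 would. Only 1 gene rose in females and fell in males. Of the female calls, 91.6% had the same sign in males. In males rises made up 61.1% of the calls, and 41.8% when scaled by total count alone, at a median of all genes of -0.20 against -0.07. With choroid plexus and endothelial scores as covariates the male count was 770, without the LPS libraries of 9 April 1327, and without the library labelled M_P60_Sal 3 1312.

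Among LPS libraries, 11 genes were higher and 4 lower in males (7 against 6 libraries), with 1710 at an unadjusted p under 0.05. Besides Xist at -8.35 ± 0.40, Tsix and the 4 Y-linked genes, these were autosomal. The scavenger receptor Msr1 was higher by 1.26 ± 0.25, adjusted p = 0.0351, the DNA demethylase Tet2 by 1.04 ± 0.20, adjusted p = 0.0149, the RNA-binding gene Taf15 by 0.91 ± 0.17, adjusted p = 0.0101 and the phosphate transporter Slc20a1 by 0.97 ± 0.18, adjusted p = 0.0159. Fbln5, an elastic fibre protein, was at -1.40 ± 0.29, adjusted p = 0.0434. With choroid plexus and endothelial scores as covariates Msr1, Tet2, Taf15 and Slc20a1 did not pass, at 1.39, 0.92, 0.84 and 0.98 (adjusted p = 0.0663, 0.105, 0.0947 and 0.0922). Adjusted over the list alone, 12 of 23 inflammatory genes were higher in males (camera adjusted p = 3.72e-07, adjusted p = 0.373 with an estimated correlation), with Ccl3 at 0.93 ± 0.23, adjusted p = 0.0882. So were 8 of 10 neutrophil markers (camera adjusted p = 1.34e-05, adjusted p = 0.333 with an estimated correlation) and 7 of 11 monocyte markers (camera adjusted p = 0.00159, adjusted p = 0.409 with an estimated correlation), while 4 of 14 endothelial and pericyte markers were lower (camera adjusted p = 1.15e-06, adjusted p = 0.333 with an estimated correlation). The mean level of the inflammatory list was 8.74, 9.03 and 8.75 log2 CPM in the libraries labelled M_P60_LPS 3, 4 and 5, collected on 9 April with 1 female library, and 6.31 to 7.95 in females. Without the libraries of that date 6 genes were called, and the medians were 0.15 for the inflammatory list (camera adjusted p = 0.242), 0.55 for neutrophil markers (camera adjusted p = 0.162) and 0.14 for monocyte markers (camera adjusted p = 0.899). Msr1, Tet2, Taf15 and Slc20a1 then fell to 0.84, 0.64, 0.62 and 0.775 and did not pass (edgeR adjusted p = 0.572, 0.572, 0.554 and 0.507). With date as a block 59 were called, with replicate number as a block 6, and by DESeq2 130. The date block kept the calls of Tet2, Taf15 and Slc20a1, but Msr1 did not pass, at 1.07 (edgeR adjusted p = 0.0587). Scaled by total count alone 8 were higher and 6 lower. Leaving out single libraries gave 45 without F_P60_Sal 6, 44 without M_P60_LPS 1, 9 without F_P60_LPS 5, 8 without F_P60_LPS 4, and 7 without M_P60_LPS 3 or M_P60_LPS 4.

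Asked directly, the response to LPS differed between the sexes for 93 genes, with 31 differences positive (more positive in males) and 62 negative. The count went from 0 to 482 when single libraries were left out, by over 1.5 times for 23 of 25 libraries, and was 2 without the LPS libraries of 9 April. Cldn5 was at -1.37 ± 0.44 in females, where it did not pass, and at -4.91 ± 0.54 in males, a difference of -3.54 ± 0.71, adjusted p = 0.0344. Egfl7 differed by -2.95 ± 0.68, adjusted p = 0.0389, and the endothelial receptor gene Tie1, at 0.91 ± 0.27 in females and -1.08 ± 0.28 in males, by -1.99 ± 0.39, adjusted p = 0.0344. The matrix gene Eln differed by -2.56 ± 0.50, adjusted p = 0.0344 and Fbln1 by -3.05 ± 0.59, adjusted p = 0.0344. Cx3cl1, the ligand of the microglial receptor Cx3cr1, rose by 2.73 ± 0.27 in females and was at 0.46 ± 0.27 in males, a difference of -2.28 ± 0.38, adjusted p = 0.0181.

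On the positive side, Ccl3 was at 0.11 ± 0.23 in females and 1.56 ± 0.25 in males, a difference of 1.45 ± 0.34, adjusted p = 0.0389. It went from 652 ± 144 to 1763 ± 662 CPM in males and from 893 ± 189 to 951 ± 239 CPM in females. Map3k8 differed by 1.48 ± 0.35, adjusted p = 0.04, the inhibitory Fc receptor Fcgr2b by 1.24 ± 0.30, adjusted p = 0.0449, Tet2 by 1.41 ± 0.28, adjusted p = 0.0344 and the X-linked ubiquitin ligase Mid1 by 2.43 ± 0.55, adjusted p = 0.0389. Ddx3y differed by 4.94 ± 1.15, adjusted p = 0.0389, beside 106 Y-linked counts in the female saline library labelled F_P60_Sal 3.

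By list, 1 of 23 inflammatory genes and 9 adjusted over the list alone differed upwards in males (camera adjusted p = 6.24e-08, adjusted p = 0.457 with an estimated correlation), at a median of 1.14. Of 14 heat shock genes, 0 passed over all genes and 10 adjusted over the list alone (camera adjusted p = 3.49e-08, adjusted p = 0.433 with an estimated correlation), at a median of 1.14, with Hsph1 at 1.79 ± 0.46, adjusted p = 0.054. The interferon list had a median of 0.76 (camera adjusted p = 2.65e-06, adjusted p = 0.571 with an estimated correlation) and the NF-kB list of 0.68 (camera adjusted p = 2.65e-06, adjusted p = 0.571 with an estimated correlation). Endothelial and pericyte markers had 2 of 14 lower and 6 adjusted over the list alone (camera adjusted p = 3.49e-08, adjusted p = 0.433 with an estimated correlation), at a median of -1.16. Glycolysis had 9 of 17 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0206, adjusted p = 0.571 with an estimated correlation), and oxidative phosphorylation a median of -0.47 (camera adjusted p = 1.05e-04, adjusted p = 0.571 with an estimated correlation). The latter turned to 0.14 with choroid plexus and endothelial scores as covariates. Neutrophil markers had a median of 0.89 (camera adjusted p = 0.0943) and monocyte markers of 1.35 (camera adjusted p = 0.0583). The libraries labelled M_P60_LPS 3, 4 and 5, all of 9 April, had the highest levels of the inflammatory, neutrophil and monocyte lists among LPS libraries, and without the LPS libraries of that date the median of the inflammatory list was 0.75 and that of the interferon list 0.38. The count depended on method and libraries. DESeq2 called 601, limma-voom 1363 and edgeR with collection date as a block 369, while edgeR with choroid plexus and endothelial scores as covariates, with counts thinned to the lowest total, or on libraries whose sex labels concur called 0. Scaled by total count alone, 17 differences were positive and 64 negative.

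**Figure D3:**
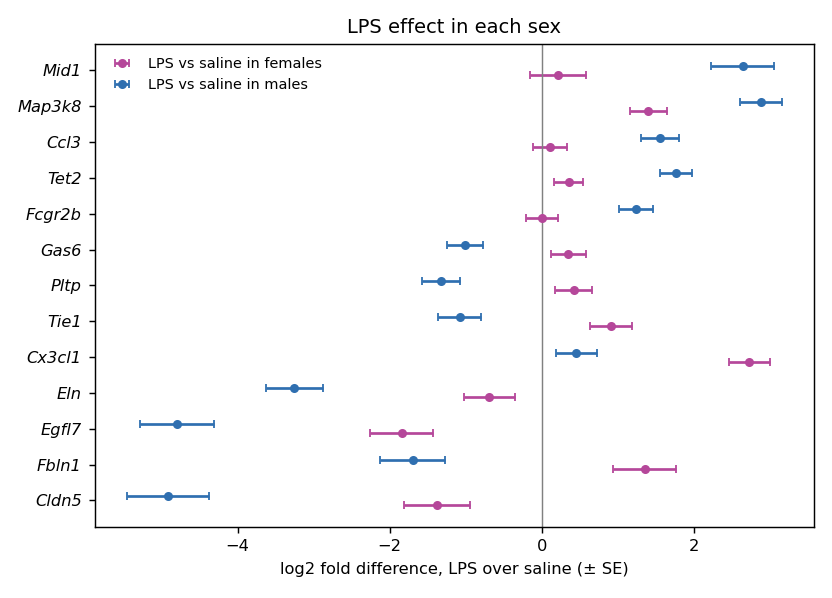
LPS effect (log2 fold, LPS over saline, ± SE) for 13 genes whose response differed between the sexes, with 1 point per sex. Cldn5 and Egfl7 lie lower in males than in females, and Ccl3 and Map3k8 lie higher.

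The developmental index is the mean log2 CPM of 2122 genes rising from E18 to P14 minus that of 3293 falling, chosen without P60 libraries. Only 692 and 1905 were not tied to choroid plexus or endothelial scores, so the index may follow these too. Its mean was 0.17 ± 0.19 (SD, n = 3) in libraries titled female and -0.24 ± 0.34 (SD, n = 4) in those titled male at E18, where the library labelled M_E18 4 was lowest at -0.66, and 3.34 ± 0.47 (SD, n = 10) and 3.53 ± 0.53 (SD, n = 10) at P14. At P60 with saline it was 3.67 ± 0.51 (SD, n = 7) in females and 3.32 ± 0.44 (SD, n = 5) in males, a difference of -0.35 (exact permutation p = 0.25, and -0.24 with exact p = 0.239 within dates). LPS males stood at 4.02 ± 0.22 (SD, n = 7), above saline males by 0.70 (exact permutation p = 0.00505, adjusted over the 5 index tests p = 0.0253). On libraries whose sex labels concur this difference was 0.60 (exact permutation p = 0.0635). LPS females stood at 3.57 ± 0.31 (SD, n = 6), at a difference of -0.10 (exact permutation p = 0.706). The LPS effect in males exceeded that in females by 0.80 (exact permutation p = 0.0177). On an index from E18 and P60 genes, males and females differed by 0.07 at P14 (permutation p = 0.732, 10 libraries each, and exact p = 0.554 within dates) and by -0.03 at P4 (exact permutation p = 0.886, and exact p = 0.875 within dates).

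**Figure D4:**
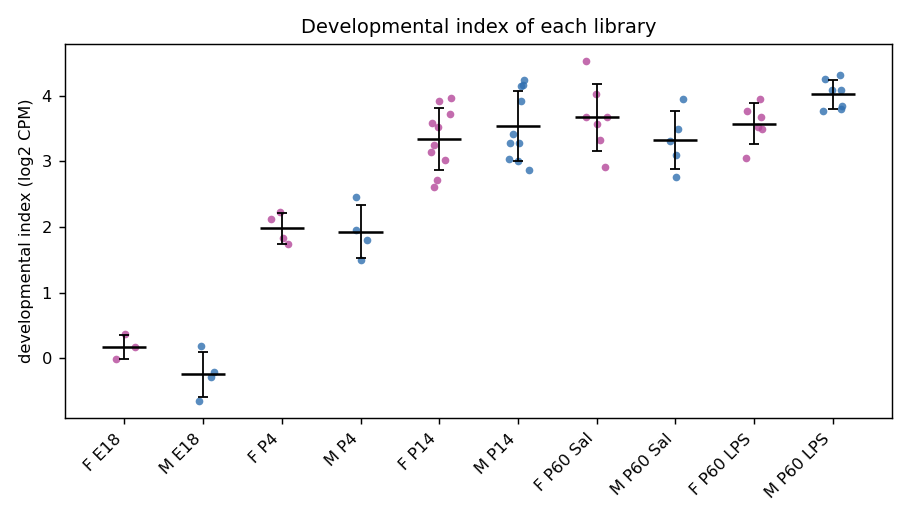
Developmental index (difference of mean log2 CPM between genes rising and falling from E18 to P14) in each group, with 1 point per library and a bar at the group mean. The E18 groups have means of 0.17 and -0.24, the P14 groups of 3.34 and 3.53, and the LPS males 4.02.

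Libraries also differed in the share of long transcripts. In the library labelled M_E18 4, 4.99% of counts fell in transcripts of at least 5000 bases and Ttr, the thyroid hormone carrier made by choroid plexus, took 24.8%. In the library labelled F_P60_Sal 6 these were 12.7% and 11.99%, and in M_E18 3 Ttr took 10.4%. In M_E18 3 the share of long transcripts was 16.2%, and in the other libraries it ran from 18.8% to 27.9%.

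**Figure D5:**
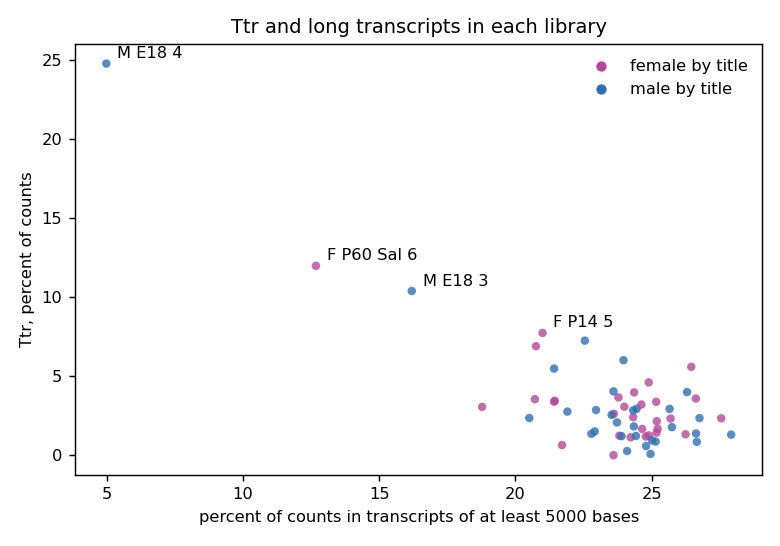
Share of counts taken by Ttr (percent) against share of counts in transcripts of at least 5000 bases (percent), with 1 point per library coloured by the sex in its title. The library labelled M_E18 4 lies apart at 24.8% Ttr and 4.99% long transcripts.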

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

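The tests of explanations in this part and the comparisons with other splits of the libraries were chosen after the results were seen. The LPS comparisons of genes and the gene lists were fixed before. Single libraries lay far from the rest of their group in 14 of 108 groups of values tested. Chance alone gives about 1 in 20 only for normally distributed values, which levels, counts and shares need not be. Some groups also flag the same library, as Ttr and long transcripts do for F_P14 5 and F_P60_Sal 6. Ttr took 7.75% of counts in F_P14 5 (next 3.99%) and 11.99% in F_P60_Sal 6 (next 3.40%). The share of transcripts of at least 5000 bases was 20.996% in F_P14 5 (next 23.8%) and 12.7% in F_P60_Sal 6 (next 21.4%). Xist stood at 132 CPM in the library labelled M_E18 4 (next 16.8) and at 14.8 in M_P14 2 (next 7.67). Y-linked counts were 56 in F_P14 10 (next 7) and 106 in F_P60_Sal 3 (next 31). Mki67 stood at 74.7 CPM in M_P60_LPS 3 (next 39.0). Spp1 stood at 53.7 CPM in F_P14 6 (next 29.8), at 260.0 in M_P60_LPS 4 (next 113) and at 16.1 in M_P60_Sal 3 (next 9.91). Ccl3 stood at 807 CPM in F_P4 2 (next 486) and at 1410.2 in F_P60_LPS 6 (next 978).

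Groups differed in the response to LPS. It differed between the sexes for 93 genes and by 0.80 on the developmental index. The differences were -3.54 for Cldn5, -3.05 for Fbln1, -2.95 for Egfl7, -1.99 for Tie1, -2.56 for Eln, -2.28 for Cx3cl1, -1.75 for Pltp and -1.37 for Gas6. They were 2.43 for Mid1, 1.45 for Ccl3, 1.48 for Map3k8, 1.24 for Fcgr2b, 1.41 for Tet2 and 4.94 for Ddx3y. List medians were 0.21 for homeostatic genes, 1.14 for inflammatory genes, 0.68 for NF-kB, 0.76 for interferon, 0.49 for complement, 0.38 for phagocytic receptors and 1.14 for heat shock genes. They were -0.47 for oxidative phosphorylation, -0.83 for glycolysis and -1.16 for endothelial and pericyte markers. With an estimated correlation 0 of these lists were called, and with choroid plexus and endothelial scores as covariates the homeostatic list turned to -0.25 and oxidative phosphorylation to 0.14.

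The genes with a different LPS response in males may reflect unequal shares of vascular cells. With choroid plexus and endothelial scores as covariates, which left 0 calls, the median of 60 of the 62 lower genes, leaving out 2 that are part of those scores, went from -2.004 to -1.33 (66.5%), which leaves this open for them, and that of the 31 higher genes from 1.34 to 1.25 (93.1%), which argues against it. Without the LPS libraries of 9 April, which left 2 calls with fewer libraries, the medians were -2.01 (100.4%) and 1.04 (77.8%). The median of the lower genes thus did not rest on the libraries of that date, while this stays open for the higher ones. Each share kept compares medians over genes, which does not measure the spread between libraries. Thinned to the lowest library total, which left 0 calls with fewer counts, the 58 lower and 30 higher genes still tested went from -1.99 to -1.94 (97.0%, quartiles -2.28 and -1.74) and from 1.33 to 1.33 (100.02%, quartiles 1.13 and 1.55). Random thinning leaves the expected fold of a gene unchanged, so these shares cannot decide whether unequal totals shaped the calls. The sex of the animals stays open as an untested explanation.

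Choroid plexus transcripts varied within groups. Choroid plexus tissue or its RNA in the sample could account for this, as 91.7% of marker comparisons were higher in the library with more Ttr, against 63.9% for other short transcripts. Loss of long transcripts alone would not raise the long markers, which were higher in 30 of 30 comparisons (100%). Whether the tissue entered at dissection stays open.

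The library labelled M_E18 4 could be a female library short of long transcripts. Its Xist ratio to the E18 females lay at the 14.2 percentile of transcripts of at least 10000 bases, inside their range. A male library with the same loss would be expected to show 148 Y-linked counts, and 0 were seen. Whether a sample was exchanged stays open.

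Each count of genes was set beside counts from other splits into groups of the same sizes. For P4 against E18, 1 of 60 splits, the real one, called as many (6686, highest other 5517), for P14 against P4 1 of 60 (5744, 21) and for P60 against P14 1 of 60 (6115, 2420), so chance can be excluded there. The same holds for LPS in the mean of the sexes (1 of 100, 1518 and 175). It holds in females (1 of 100, 533 and 88) and males (1 of 100, 2054 and 707). For sex by LPS (1 of 100, 93 and 0) chance stays open, as leaving out single libraries gave 0 to 482. For sex at P14 (1 of 60, real 6, highest other 1) and at P60 with saline (2 of 60, 6 and 7) the splits decide nothing. All 6 calls there were sex-linked genes, which a split that mixes the sexes tends to lose. For sex in LPS libraries the share was under 0.05 (3 of 100, 15 and 32), but only 9 of the 15 calls were autosomal, where other splits had up to 28. Where the sexes were exchanged only within collection dates, the real split alone called as many at P14 (1 of 60, 6 and 1), at P60 with saline (1 of 60, 6 and 5) and with LPS (1 of 100, 15 and 8), and for sex by LPS (1 of 100, 93 and 0). The LPS split with 8 calls had 8 autosomal ones, against 9 in the real split. Chance cannot be excluded for sex at E18 (15 of 35, 10 and 3695). For sex at P4 the replicate numbers pair the libraries, and 1 of the 8 splits that part all 4 pairs, the real one, called as many (6, highest other 0), which are too few splits for a share under 0.05. The 27 splits that keep some pairs together include 1 with 19 genes (2 of 35 over all). For sex by age every split reaches the real count of 0 (20 of 20, highest other 760), so the splits decide nothing. At E18 a split calling 3695 genes points to structure among the samples other than the labelled sex.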

How the results depend on the processing

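The alternatives for transcript rows, covariates, index genes tied to them, thinning, date blocks for sex by age, sex by LPS and the list tests, scalings of the list tests, and leaving out libraries by Ttr or date were chosen after seeing the data, and the cause of a change was not tested unless stated. The stage comparisons kept their counts within 1.5 times, with leave-one-out ranges of 5580 to 7142 genes for P4 against E18, 4957 to 6326 for P14 against P4 and 5688 to 6840 for P60 against P14. Of 12915 values of named genes 12255 kept direction and side of the threshold, 655 lost the threshold and 5 reversed. Of 1429 list values 1144 kept both, 271 lost the call and 14 reversed. Camera called 146 of 362 list tests, 27 with an estimated correlation, and fry 94. Sex at E18 (10 genes) gave 500 with DESeq2, 1253 with limma-voom, 0 with sex from characteristics, 6 on concurring labels, 6 with the replicate block, 5 with the date block, 0 with only the compared groups, 6 without libraries of over 10% Ttr, and 6 to 2475 leaving out single libraries. Sex at P4 gave 0 with sex from characteristics, and 6 to 6 leaving out libraries, as at P14. Sex at P60 with saline (6) gave 26, 184, 0 and 11 with DESeq2, limma-voom, characteristics and the date block, and 6 to 35 leaving out libraries. Sex in LPS libraries (15) gave 130 with DESeq2, 76 with all 60 libraries fitted, 0 with characteristics, 6 with the replicate block, 59 with the date block, 45 without Ttr libraries, 6 without 9 April, and 7 to 45 leaving out libraries.

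LPS in the mean of the sexes (1518) gave 2403 with limma-voom and 1302 to 1702 leaving out libraries. In females (533) it gave 994 and 391 to 566. In males (2054) it gave 3453, 770 with both covariates, 1327 without 9 April, and 1312 to 2487, the lowest without M_P60_Sal 3. Sex by LPS (93) gave 601 with DESeq2, 1363 with limma-voom, 255 with all 60 libraries, 0 with characteristics, 0 on concurring labels, 369 with the date block, 129 with the replicate block, 0 with both covariates, 0 thinned (fewer counts), 482 without Ttr libraries and 2 without 9 April. Leaving out single libraries gave 0 to 482. It was 0 without M_P60_LPS 2, 3, 4 or 7, F_P60_LPS 4 or 6 or M_P60_Sal 3, 1 without F_P60_Sal 5, F_P60_LPS 3 or M_P60_Sal 4, and 2 without F_P60_Sal 1, 3 or 4 or M_P60_Sal 5. It was 17 without F_P60_LPS 5, 48 without M_P60_LPS 6, 141 without M_P60_Sal 1, 144 without M_P60_LPS 5, 222 without M_P60_LPS 1, 258 without F_P60_LPS 1, 411 without M_P60_Sal 2, 461 without F_P60_Sal 7 and 482 without F_P60_Sal 6. The replicate block gave 6843, 4596 and 5931 genes for the stage comparisons in order, 6 for sex at P14, 7 for sex at P60 with saline, 1319, 467 and 1771 for LPS in the mean, females and males, and 0 for sex by age. Sex by age (0) gave 743 with limma-voom and 0 to 486, the highest without M_E18 2. Scaling by total count moved the median of all genes to -0.18 for sex at E18, from -0.01, and to 0.18 for sex by age, from 0.00.

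The index difference between the sexes at P60 was -0.56 (exact permutation p = 0.048) with sex from characteristics, and -0.50 to -0.21 leaving out libraries. The LPS effect in males was 0.60 on concurring labels, and 0.56 to 0.85 leaving out libraries. In females it turned to 0.0406 without genes tied to the choroid plexus or endothelial scores, and ran from -0.22 to 0.05, with 0.0082 without F_P60_LPS 2 and 0.0453 without F_P60_Sal 5. At P14 the difference turned to -0.0637 with the top 100 genes and ran from -0.0111, without M_P14 9, to 0.13. At P4 it turned to 0.0805 with the top 100, 0.0241 at 4-fold, 0.0837 with characteristics and 0.0533 on concurring labels, and ran from -0.18 to 0.11, with 0.1065 without M_P4 1 and 0.0109 without F_P4 2. With sex from characteristics Ech1, Ssr2 and Rnf5 at E18 turned to -0.92, -1.14 and -0.45, and Ddx3y to 1.48 for LPS in females and -0.76 for sex by LPS. Lysosomal genes at E18 turned to -0.0479 on concurring labels, -0.15 without Ttr libraries and -0.16 with the date block. On concurring labels neutrophil markers at P4 turned to -0.52 and ribosomal genes at P60 with saline to 0.0767, and the latter to 0.0233 without Ttr libraries. With the choroid plexus score, homeostatic genes at P14 turned to -0.11 and oxidative phosphorylation to 0.0754. With both scores oxidative phosphorylation at P14 turned to 0.0235, homeostatic, NF-kB and complement genes at P60 with saline to 0.10, 0.11 and 0.14, and homeostatic genes and oxidative phosphorylation for sex by LPS to -0.25 and 0.14. Depth limits what passes for sex by LPS, where thinning left 0 calls.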
